A study of Mus musculus with 12 samples.

How the data were processed

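RNA from bone marrow-derived mast cells of C57BL/6 mice was measured in 6 samples grown in IL3 and 6 grown in IL3 with SCF. Per the labels' protocols, targets were made from 50 ng of RNA by whole-transcript amplification and hybridised to Affymetrix arrays. The deposited values are linear probe set intensities, and GCOS 1.4 is named in the submitters' processing notes. The background correction and scaling target are not given in the sources used here. In the values, the mean of each array trimmed by 2% at each end was 1250.01, so the arrays had been scaled to a common level. Array medians spanned 0.39 on the log2 scale, below the limit of 0.5 set for quantile normalization, so the intensities were kept as deposited. No detection calls were used.

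The table held 45101 probe sets, 64 of them controls. In the annotation given, 34958 had 1 gene symbol, 932 several and 9211 none, for 18194 genes. Entrez identifiers of 34754 matched a RefSeq table of assembly GRCm38.p6, with 0 differences in symbol, and no coordinates are printed because no build is named with the data. Signals were taken as log2(signal + 16), on which scale fold changes of dim genes are understated. A probe set was kept when at least 6 arrays exceeded that array's 40th percentile, which left 27226, and a signal at or below that percentile is called dim. Each gene was represented by its brightest single-symbol probe set, for 11430 genes.

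Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates) with Benjamini-Hochberg adjustment and a threshold of 0.05, and at least 2-fold means an absolute log2 change of 1 or more. Gene lists with at least 5 tested members were compared with camera at a preset correlation of 0.01. There were 31 lists, 20 of mast cell processes and 11 of other cell types, and 23 could be tested. None of the list calls held with an estimated correlation. Counts adjusted over the list alone use the same p-values adjusted among the list's members. Single measures per array were compared with an exact permutation test, two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

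The named genes were the 8 largest rises and 8 largest falls among genes that passed, did not overlap between groups and had a mean in the higher group at or above the median of all genes. To these were added 8 genes set beforehand, of which 6 were tested and the others are not reported here. From each list came at most 2 risen and 2 fallen members with the largest change, or 1 and 1 for other cell types, and the member with the smallest p where none passed. The comparisons, lists, rule and alternatives were chosen before the data were examined, except the tests and alternatives named below as added.

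On simulated arrays with the same means and spreads, 71.1% of genes changed by 0.5 on the log2 scale were recovered, 93.8% at 1 and 100% at 2. There were 8 false calls among 11130 unchanged genes. The noise was drawn independently for each probe set and array, without correlation between genes or differences of whole arrays. The count of false calls need therefore not hold for these data.

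Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a 60th percentile filter, other choices of probe set, trend and robust eBayes, array weights, the replicate number as a block, each array left out, an estimated correlation, fry and the rank version of camera. When an array was left out the filter stayed at 6 arrays. That version drops genes seen in 1 group only, so a filter at the smaller group's size was tried after its results were seen, and both are given. Fits without IL3 replicates 4 and 5, and without 3 and 6, the classes of signal brightness, and list counts under each alternative were also added after the data were seen. IL3 replicates 4 and 5 were left out because they stood apart. Replicate 4 had the lowest score on the second principal component (-36.6, 17.3% of the variance) and the lowest mean correlation within its group (0.9775). Replicate 5 had the lowest array weight (0.384). The mean correlation within groups was 0.984 ± 0.003 in IL3 and 0.989 ± 0.001 in IL3+SCF (SD, n = 6). Markers for the tests of other cells were first a shorter hand-picked set that lacked Lyz1 and Lyz2, and the full lists were then used. Those tests first set marker signals against those of other probe sets, which share no common scale, and then used each marker's own change. All tests of other cells were set after the results were seen. No arrays held identical values, and Eif2s3y, Kdm5d and Uty were bright and Xist low on all 12 arrays.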

Results

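Gene expression was measured on 12 single-colour Affymetrix arrays, each hybridised with RNA from mast cells grown out of C57BL/6 mouse bone marrow. Mast cells are tissue-resident effector cells of allergy that carry the high-affinity IgE receptor and the receptor tyrosine kinase KIT. In 6 samples the cells had been kept for 4 to 6 weeks in interleukin 3 (IL3, 30 ng/ml), and in the other 6 stem cell factor (SCF, the ligand of KIT, 100 ng/ml unless indicated otherwise) was present as well. The labels give a culture purity above 99% by toluidine blue staining and surface receptors. The median probe set signal lay between 151 and 203 on the 12 arrays. The first principal component held 52.7% of the variance and parted the cultures (exact permutation test, two-sided, p = 0.002165, the smallest that 6 against 6 arrays can give). The number of arrays limits the precision of every value. The labels do not say whether the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

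The comparison asked how long-term SCF alters the transcripts of mast cells otherwise grown in IL3. Of 11430 genes tested, 2155 were higher and 1895 lower with SCF (limma, Benjamini-Hochberg adjusted p below 0.05), which is 35.4% of the genes. At least 2-fold changes were seen for 219 risen and 336 fallen genes. The groups did not overlap for 2181 genes, or 19.1%, where chance gives 0.216%. With each array centred on its median the counts were 1369 risen and 1409 fallen.

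The largest rise among the brighter genes was that of Mcpt4, a chymase of mouse connective tissue mast cells. Its signal was 443 ± 178 in IL3 and 12653 ± 1306 in IL3+SCF (SD, n = 6 each), a log2 fold change of 4.85 ± 0.18 (SE, adjusted p = 5.083e-09). Mrgprb1, a Mas-related G protein-coupled receptor gene, rose by 4.72 ± 0.26 on the log2 scale, from a signal that was dim on 3 of the 6 IL3 arrays, and with a pseudocount of 1 it ranked above Mcpt4 (5.01 against 4.90). Gnai1, an inhibitory G protein alpha subunit, rose by 4.12 from a signal dim on 3 IL3 arrays, and its 3 probe sets gave between 1.36 and 4.12. Ddc, the aromatic L-amino acid decarboxylase, rose by 3.81 ± 0.24. Nrp1, the neuropilin-1 coreceptor of semaphorins and VEGF, rose by 3.68 ± 0.25, its probe sets giving between 2.20 and 3.97. Cntn4, Fblim1 and Calcrl rose by 3.60, 2.78 and 2.68, the other probe set of Cntn4 giving 1.71. In all 8 genes the 6 IL3+SCF arrays lay above the 6 IL3 arrays, as the rule that selected them required.

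The largest fall was that of Smpx, a small muscle protein gene, with a signal of 5787 ± 2444 in IL3 and 31.1 ± 19.5 in IL3+SCF, where it was dim on all 6 arrays (log2 fold change -6.90 ± 0.34, adjusted p = 4.127e-08). The neighbouring transmembrane genes Tmem176b and Tmem176a fell, with log2 fold changes of -4.82 and -4.73. Plac8 fell by 4.63 to a signal that was dim on 5 arrays, and the proton-sensing receptor gene Gpr65 fell by 4.06. The nuclear receptor gene Rora, the fractalkine receptor gene Cx3cr1 and the GTPase gene Gimap3 fell, with log2 fold changes of -3.97, -3.90 and -3.89. These 8 genes also had no overlap between the groups, by the same rule.

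The transcripts that define the cell type did not pass the test. Kit had a signal of 19388 ± 1202 in IL3 and 19172 ± 540 in IL3+SCF, a log2 fold change of -0.01 (adjusted p = 0.854). The 3 chains of the IgE receptor, Fcer1a, Ms4a2 and Fcer1g, had log2 fold changes of -0.02, 0.02 and 0.06, and the protease gene Cpa3 had -0.02. A dimmer probe set of Ms4a2 had a log2 fold change of 0.15 (limma adjusted p over probe sets = 0.03669). These genes are among the brightest on the arrays. Of 247 genes with a mean signal of at least 20000, just above that of Kit, 46 changed and 1 changed at least 2-fold. Among 1153 genes with a mean signal of at least 10000, 26% changed and 0.694% changed at least 2-fold. Under 300 it was 29% and 9.13%. Fyn, a Src family kinase, rose by 1.04 ± 0.09 (adjusted p = 3.8e-06).

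**Figure D1:**
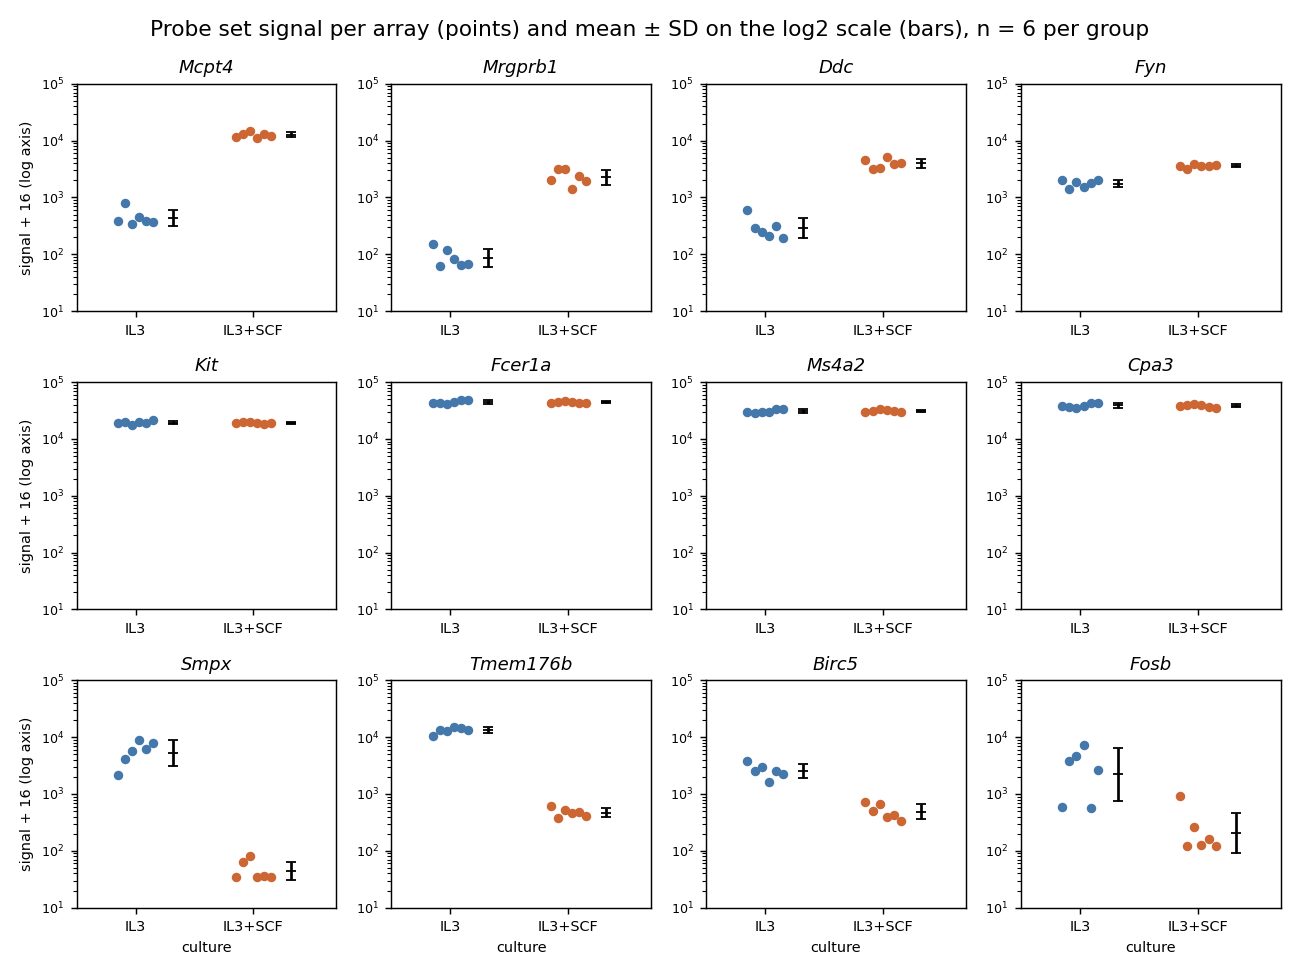
Signal plus 16 of 12 genes on each array (points, log axis) in IL3 and IL3+SCF cultures, with the mean and SD taken on the log2 scale (bars, n = 6 per group). Mcpt4, Mrgprb1, Ddc and Fyn lie higher and Smpx, Tmem176b, Birc5 and Fosb lower with SCF, Fosb with overlap between the groups, while Kit, Fcer1a, Ms4a2 and Cpa3 had log2 fold changes between -0.02 and 0.02.

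Genes of the cell cycle and DNA replication fell as a group. Of 55 tested, 39 fell, 2 rose and 14 did not pass, and adjusted over the list alone 42 fell and 4 rose. Birc5, the chromosomal passenger protein survivin, fell by 2.40 ± 0.22 on the log2 scale, and Ccna2, cyclin A2, by 2.17 ± 0.18. Cdc6, a replication licensing factor, rose by 0.65 ± 0.11, and Ccnd2, cyclin D2, rose by 0.27 ± 0.06 (other probe sets up to 0.72), a call lost with each array centred on its median. The list median was -0.74 (camera adjusted p = 6.59e-13, and adjusted p = 0.527 with an estimated correlation). The mean log2 value over the list was 10.08 ± 0.18 in IL3 and 9.24 ± 0.13 in IL3+SCF (SD, n = 6, exact permutation p = 0.00216, the smallest possible).

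Immediate early genes, the transcripts that follow growth factor and calcium signals within minutes, together with feedback genes of the ERK pathway, also fell. Of 29 tested, 15 fell, 2 rose and 12 did not pass, and adjusted over the list alone 17 fell and 2 rose. Fosb fell by 3.44 ± 0.71 and Nr4a1 by 2.69 ± 0.56, both with overlap between the groups. Etv5, an ETS factor, rose by 1.11 ± 0.16 (other probe sets down to 0.53), and Spred1 rose by 0.18 ± 0.05 (other probe sets up to 0.55), a call lost with each array centred on its median, with the replicate block and without IL3 replicates 4 and 5 or 3 and 6. The list median was -0.45 (camera adjusted p = 0.000273, and adjusted p = 0.559 with an estimated correlation). The mean over the list was 12.04 ± 0.33 in IL3 and 11.30 ± 0.29 in IL3+SCF (exact permutation p = 0.00649), and IL3+SCF replicate 1 stood above the other arrays of its group.

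Genes of cholesterol synthesis and uptake rose. Of 21 tested, 12 rose, 0 fell and 9 did not pass, and adjusted over the list alone 13 rose. Fdft1, squalene synthase, rose by 0.77 ± 0.11 and Fdps, farnesyl diphosphate synthase, by 0.75 ± 0.18. The list median was 0.37 (camera adjusted p = 0.000273, and adjusted p = 0.559 with an estimated correlation). With each array centred on its median 7 of the 21 rose.

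The list of mast cell granule proteases and contents had 6 risen and 0 fallen members of 21 tested, also when adjusted over the list alone. It also holds genes whose products are not themselves granule contents, among them the receptor gene Mrgprb1 and the decarboxylase gene Ddc. Beside Mcpt4, Mrgprb1 and Ddc these were Tpsab1, Mcpt2 and Tpsg1, named after their values were seen. Tpsab1, a tryptase gene, rose by 4.18 ± 0.34 from a signal that was dim on all 6 IL3 arrays, Mcpt2 rose by 0.88 ± 0.11 and Tpsg1 by 0.51 ± 0.09. The list median was 0.13 and its mean 0.96 (camera adjusted p = 0.0182, and adjusted p = 0.559 with an estimated correlation). This call was lost without IL3+SCF replicate 2, 3 or 4, where the adjusted p was 0.0676, 0.0984 and 0.0699.

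**Figure D2:**
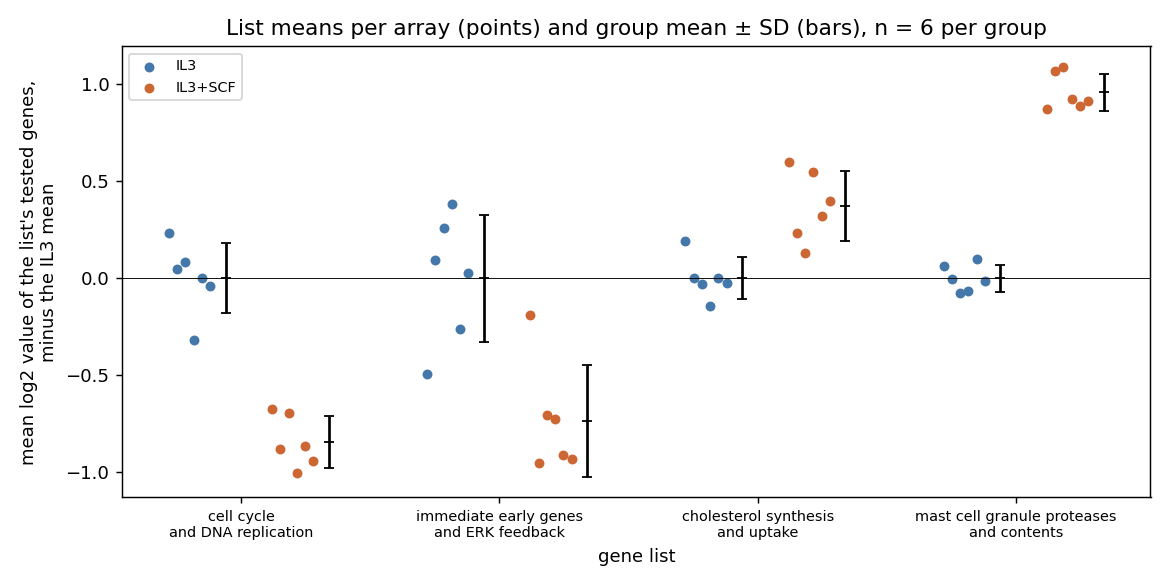
Mean log2 value of the tested genes of 4 lists on each array (points), less the IL3 mean of that list, with group mean and SD (bars, n = 6 per group). The list means changed by -0.84 for the cell cycle, -0.74 for immediate early genes, 0.37 for cholesterol synthesis and 0.96 for the granule list. The granule list includes the receptor gene Mrgprb1 and the decarboxylase gene Ddc.

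The other 19 of the 23 lists tested did not pass camera, which compares a list with all other genes. The exact permutation test of the list means makes no such comparison. In it the 4 lists above passed, and so did eicosanoid synthesis, cytokines and chemokines, STAT5 targets, monocyte and megakaryocyte markers (adjusted p = 0.00711 each) and the BCL2 family (0.0199). In the IgE receptor and proximal signalling list, 5 of 35 rose, 6 fell and 24 did not pass, also when adjusted over the list alone. List counts rest on the brightest probe set of each gene unless another choice is given. Other kept probe sets passed in the opposite direction for Vav1 and Pag1 in this list (Pag1 3 of 4, its probe sets between -0.78 and 0.14). The same held for genes of other lists, among them Rac2, Cdc42, Arpc2, Dock2, Dock8, Ikzf2, Meis1, Cd84, Lta4h and Tgfb1. Grap2 and Rasgrp1, an adaptor and a Ras activator, fell (log2 fold changes -1.66 and -0.91, with -0.42 from a dimmer Rasgrp1 probe set), and Sos1 rose by 0.36, a call lost with the mean of its probe sets or the most variable one. The number risen was 1 with each array centred on its median, 2 with no filter on dim probe sets, 8 with array weights, 2 without IL3 replicate 3 or 4 or IL3+SCF replicate 1 or 4, 3 without IL3+SCF replicate 2 and 8 without IL3 replicate 5. Of 3 Src family kinases tested, Fyn rose, Fgr fell to a signal dim on all 6 IL3+SCF arrays (log2 fold change -2.45) and 1 did not pass. In granule exocytosis 8 of 26 rose and 3 fell, also adjusted over the list alone, with Sytl2 up by 1.18 and Syt9 down to a signal dim on 5 IL3+SCF arrays (log2 fold change -2.81), and 6 and 1 with each array centred on its median. In the cytoskeleton list 9 of 54 rose and 9 fell, also adjusted over the list alone, and 5 and 6 with each array centred on its median, with Rhoc at 1.74 and Iqgap2 at -0.88 (-0.44 from a dimmer probe set).

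Among receptors for inhibitory and activating signals, 11 of 24 rose and 3 fell, and adjusted over the list alone 13 rose and 3 fell (camera adjusted p = 0.0792). This list passed with quantile normalization (adjusted p = 0.0411), with a 60th percentile filter (0.00501) and without IL3+SCF replicate 6 (0.0472). Pilra rose by 0.85, a call lost without IL3 replicates 4 and 5 or 3 and 6, Pirb, a paired inhibitory receptor, rose by 0.74 ± 0.09, and Fcgr1 and Clec4d fell (log2 fold changes -1.32 and -1.16), Fcgr1 to a signal dim on 5 IL3+SCF arrays. Of 28 receptors for KIT ligand and cytokines, 10 rose and 5 fell, with the same counts adjusted over the list alone. Tnfrsf9 rose by 2.79 and Il5ra by 1.04, while Il7r and Il2ra fell (log2 fold changes -2.20 and -1.69, with -1.36 from a dimmer Il7r probe set). Of 25 receptors for mast cell agonists 6 rose and 4 fell, and 7 and 5 adjusted over the list alone, with P2ry1 at 0.87 and Cxcr4 at -1.39. Beside G protein-coupled receptors this list holds the ion channel genes P2rx1, P2rx4 and P2rx7. Of 31 cytokines and chemokines 11 rose and 5 fell, and 12 and 6 adjusted over the list alone (camera adjusted p = 0.146). Ccl1 rose by 2.53 ± 0.23 and Tnfsf8 by 1.94 ± 0.14, and Cxcl12 fell by 1.52 ± 0.20. In eicosanoid synthesis 1 of 15 rose and 4 fell, and 1 and 5 adjusted over the list alone, and 2 rose with the most variable probe set, with trend and robust eBayes or without IL3 replicate 3. Mgst3 rose by 0.48, and Hpgd and Ptgs2 fell (log2 fold changes -2.30 and -2.18), Hpgd to a signal dim on all 6 IL3+SCF arrays.

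Of 31 transcription factors of mast and blood cells, 6 rose and 5 fell, also adjusted over the list alone, and 3 and 4 with each array centred on its median. Maf and Lmo2 rose by 0.68 each, and Cebpb and Cebpa fell (log2 fold changes -1.81 and -1.14, with -0.57 from a dimmer Cebpb probe set). Of 14 STAT5 targets 2 rose and 6 fell, and 3 and 6 adjusted over the list alone. Socs2 rose by 0.40 (other probe sets up to 1.51), Il2ra and Pim3 fell (log2 fold changes -1.69 and -1.12, with -1.74 from a dimmer Pim3 probe set), and 4 rose without IL3 replicate 5 or with array weights. Of 13 BCL2 family genes 2 rose and 2 fell, and 4 and 3 adjusted over the list alone. Bcl2l11 and Pmaip1 rose by 0.74 and 0.59, the first a call lost with the most variable probe set, Bcl2 fell by 0.51 (other probe sets between -0.59 and -0.13), and 5 rose without IL3 replicate 5 and 4 without IL3+SCF replicate 5, with array weights or with the mean of each gene's probe sets. Of 29 genes of glycolysis and the hypoxia response 6 rose and 5 fell, and 6 and 7 adjusted over the list alone, with Eno2 at 2.09, Aldoc at 1.02 and Egln3 at -1.42, a call lost with no filter or without single arrays, and 6 and 3 with the mean of each gene's probe sets or the most variable one.

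Of 26 interferon response genes 6 rose and 5 fell, and 6 and 7 adjusted over the list alone, with Oas1a at 0.80 and Oasl1, dim on 5 IL3+SCF arrays, at -0.67, and 5 and 3 with a 60th percentile filter. Of 29 integrin and adhesion genes 9 rose and 5 fell, and 9 and 6 adjusted over the list alone, and 9 and 2 with a 60th percentile filter. Itga6 rose by 1.54 and L1cam by 1.04, while Itgb3 fell by 1.69 and Cdh1 fell to a signal dim on all 6 IL3+SCF arrays (log2 fold change -2.90). Of 11 genes of MHC class II presentation and costimulation 2 rose and 2 fell, also adjusted over the list alone, and 4 fell with no filter on dim probe sets. H2-Oa had a log2 fold change of -1.80 and H2-DMa of -0.84. Pdcd1lg2 had 0.63, a call lost with the replicate block and without IL3 replicates 4 and 5 or 3 and 6. For the lists of IgE receptor signalling, granule exocytosis, glycolysis, interferon response and MHC class II, the median, the mean and the test differed in sign.

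**Figure D3:**
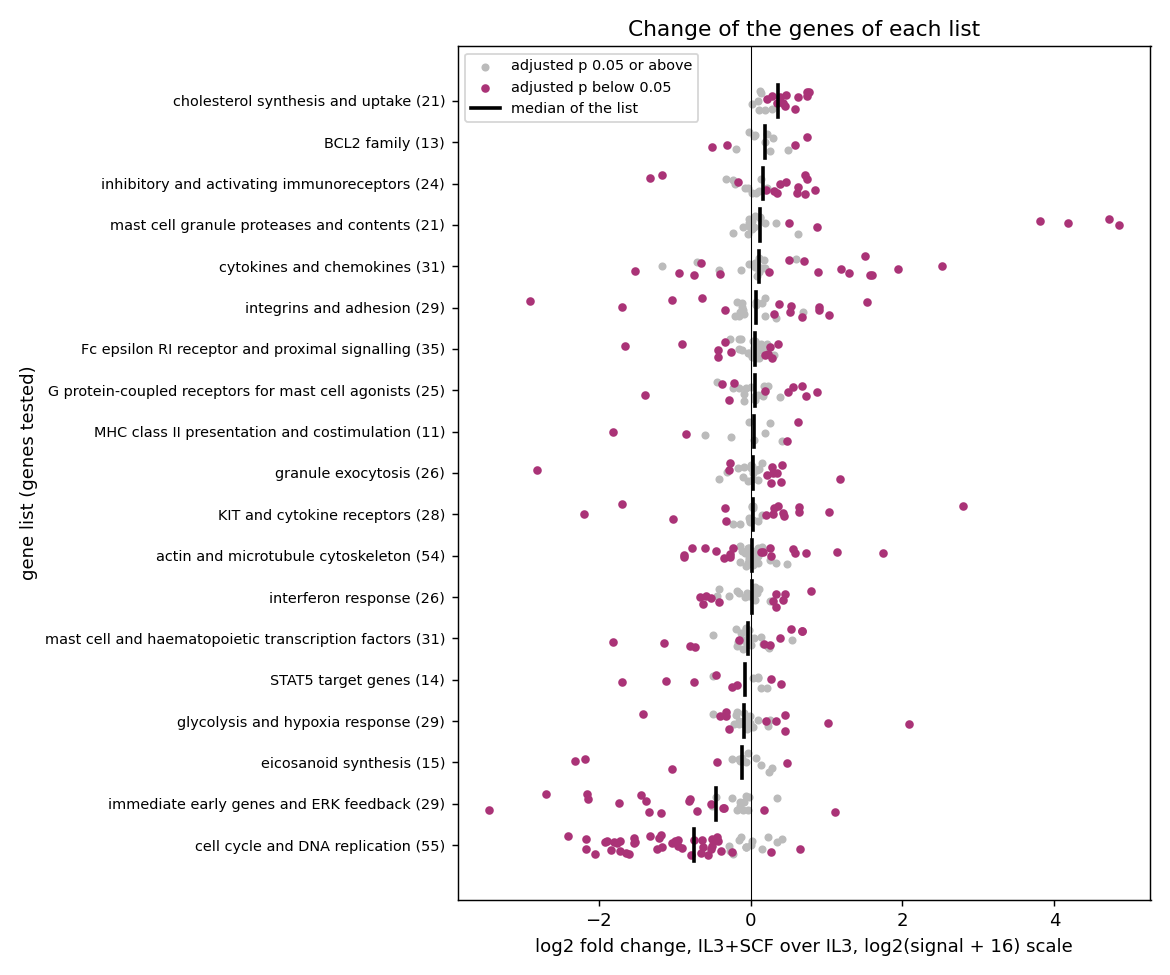
Log2 fold change (IL3+SCF over IL3, log2(signal + 16) scale) of every tested gene of the study lists with at least 5 tested genes, with adjusted p below 0.05 in colour and the list median as a bar. The cell cycle list has the lowest median, -0.74, and cholesterol synthesis the highest, 0.37.

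Markers of other blood and tissue cells were read in the same way. Of 9 monocyte and macrophage markers tested 1 rose and 4 fell, and 2 and 4 adjusted over the list alone, with Cd68 at 1.28 and Cx3cr1 at -3.90. Of 8 basophil markers 2 rose and 2 fell, also adjusted over the list alone, with Il3ra at 0.44 and Gda at -0.44. Of 5 megakaryocyte and platelet markers 1 rose and 2 fell, and 1 and 4 adjusted over the list alone, and this list passed with no filter on dim probe sets (camera adjusted p = 0.0330). Of 6 progenitor markers 0 rose and 1 fell, Hlf, a call lost with no filter, without single arrays and when adjusted over the list alone. Fewer than 5 markers were tested for the remaining types, with the same counts adjusted over the list alone unless given. Of 4 B cell markers 2 fell, with Ighm at -2.55, and 1 with each array centred on its median. Of 4 stromal markers 2 fell, with Pdgfrb at -2.30, and 1 with a 60th percentile filter. The mean IL3+SCF signals of Ighm and Pdgfrb were 43.3 and 39.1, where the 40th percentile of those arrays averaged 83.7. The 1 T and NK cell marker, Nkg7, fell, a call lost with a pseudocount of 1, with no filter and, with the filter at the smaller group's size, in 8 of 12 cases of 1 array left out. Of 3 erythroid markers 1 rose and 1 fell, and the rise, of Epor, was lost with quantile normalization, median centring, trend and robust eBayes and the replicate block. Of 3 eosinophil markers 1 rose and 0 fell, with 1 fallen adjusted over the list alone and under most other settings with all arrays. The untested eosinophil marker Prg2 had signals of 178 and 220 on IL3 replicates 3 and 6 and at most 31.2 with SCF. The 2 dendritic cell markers tested did not pass. The untested H2-Aa was above the dim level on 5 IL3 and 0 IL3+SCF arrays, and Cd8a on 0 IL3 and 2 IL3+SCF arrays. Mmp8, the 1 neutrophil marker tested, did not pass either, but untested ones were bright on some IL3 arrays. S100a9 had signals of 2776 and 3475 on IL3 replicates 3 and 6, 51.3 to 516 on the other IL3 arrays and at most 51.0 with SCF, and S100a8 had 1773 and 2153 on the same 2 arrays. With no filter the neutrophil list passed (camera adjusted p = 0.0468), and without IL3 replicates 4 and 5 it had 2 fallen members of 3 tested. Without IL3 replicates 3 and 6 the same 4 lists passed camera and 4 of 9 monocyte markers fell, while 2 genes of the IgE receptor list, 5 of the cytoskeleton and 3 transcription factors rose and 2 glycolysis genes fell. Counts of 2 or fewer moved by 1 in several other lists under the alternatives.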

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

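The check of single arrays was planned, and the tests weighed here were set before their results were seen. In each group of 6 arrays the gap of the extreme array to its nearest neighbour was divided by the range of the group, with 0.625 as the limit. Of 224 groups checked 18 passed it, where chance gives about 11.2.

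IL3+SCF replicate 1 stood apart in 6 of these. Its mean over the immediate early genes was 11.84, against 11.08 to 11.33 on the other arrays (share of the range 0.676). The share was 0.626 for Fosb, 0.632 for Bcl2l11, 0.827 for Pdcd1lg2, 0.681 for Mmp8 and 0.678 for Tfrc. IL3 replicate 1 stood apart for Il7r (0.671), Ltb4r1 (0.632), Pim3 (0.649) and Pdcd1lg2 (0.638). IL3 replicate 5 had the highest 3'/5' signal ratios of the controls Actb (0.77) and Gapdh (0.751). Single values were 0.68 for Mcpt4 on IL3 replicate 2, 0.822 for Cntn4 on IL3 replicate 4 and 0.632 for Pdgfrb on IL3 replicate 6. The IL3+SCF values were 0.691 for Fgr on replicate 4, 0.858 for Mgst3 on replicate 6 and 0.714 for Ptgs2 on replicate 3.

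The fall of the immediate early genes was weighed against array quality and harvest. With the 3'/5' ratios in the fit, 15 of 15 fallen members still fell, with a median of -1.23 against -1.33 before. With the level of dim signals in the fit the median was -1.31. These measures differed little between the groups. The Actb ratio was 1.76 ± 0.22 in IL3 and 1.65 ± 0.10 in IL3+SCF (SD, exact permutation p = 0.3506). The Gapdh ratio was 1.59 and 1.57 (exact permutation p = 0.7706), and the 40th percentile 82.5 and 83.7 (exact permutation p = 0.8658). A measure so alike in both groups can take little from a group difference, and the 15 members were chosen because they fell. The values show only that the fall does not follow these measures. The mean over the fallen genes overlapped between groups by -0.0830 (lowest IL3 array less highest IL3+SCF array), and the overlapping arrays were IL3 replicate 1 (11.57) and IL3+SCF replicate 1 (11.66). Overlap or none, harvest conditions shared by a group cannot be told apart from SCF, because the labels name no harvest batches.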

How the results depend on the processing

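Chosen after the data were seen were the fits without IL3 replicates 4 and 5 or 3 and 6 and the filter at the smaller group's size. None of the 102 named genes reversed, and 86 kept their call under every alternative that gave them a value. Leaving out 1 array with the filter kept at 6 arrays gave 3577 to 4369 changed genes, 508 to 549 changed at least 2-fold and 3 to 5 lists, and left up to 6 named genes without a value. The granule contents list was the one lost, without IL3+SCF replicate 2, 3 or 4. With the filter at the smaller group's size the ranges were 3628 to 4401, 556 to 586 and 4 to 5, so the loss of that list depends on the filter. The list of inhibitory and activating receptors passed in the cases given with it, and also without IL3 replicates 4 and 5 with the filter kept at 6 (adjusted p = 0.0356). Without IL3 replicates 4 and 5 there were 3789 changed genes, 578 at least 2-fold and 4 lists, or 3739, 501 and 5 with the filter kept at 6. Without replicates 3 and 6, which had the highest neutrophil markers, there were 3103, 564 and 4, or 3026, 486 and 4.

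A 60th percentile filter gave 333 genes changed at least 2-fold, with fewer genes tested. Every kept probe set on its own gave 8400 changed and 1121 at least 2-fold, with more units tested. The lists shifted numbered 0 with an estimated correlation, 15 with fry, which does not compare a list with other genes, and 3 with the rank version. The cause of the other differences was not tested. Median centring gave 2778 changed genes.

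With the replicate number as a block 3326 genes changed, 555 at least 2-fold, and 4 lists shifted. Only 2 of 6 same-numbered pairs correlated above 0.1 (0.313 for number 4 and 0.356 for number 6), and 3 of 12 arrays correlated best with their own number. The other pairs had at most 0.00347, so the numbers gave no general sign of pairing. Pairing within numbers 4 and 6 cannot be excluded, because these correlations were not tested. Under the block 2 genes of the IgE receptor list rose and 5 fell, 7 and 1 in granule exocytosis, and 5 and 8 in the cytoskeleton list.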

Other observations

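Chosen after the results were seen were the tests of other cell types and the genes of the next paragraph. The tests of splits, of the cell cycle genes and of the axon guidance class were set before.

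Some genes of the cytokine list, which did not pass as a list (camera adjusted p = 0.146) and had 11 risen and 5 fallen members of 31, are given with their values. Csf1 had a signal of 1627 ± 504 in IL3 and 4748 ± 294 in IL3+SCF (log2 fold change 1.60 ± 0.18, n = 6, limma adjusted p = 3.078e-05). Il13 rose by 1.51 ± 0.18, Pdgfa by 1.19 ± 0.06, and Csf2 by 1.57 ± 0.20 from a signal dim on all 6 IL3 arrays. The fallen members were Cxcl12 (-1.52), Ccl6 (-0.94), Osm (-0.74), Lif (-0.65) and Vegfa (-0.40), and Tnf (-1.16) and Il1b (-0.70) did not pass. The Vegfa call was lost with the most variable probe set and without IL3 replicates 3 and 6. The brighter of 2 Tpsb2 probe sets had a log2 fold change of 0.05 at a signal of 35536 in IL3, and the dimmer had 0.91 ± 0.09 at 918.

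In 100 of the 462 splits of the arrays, the real one included, 1 gave as many changed genes (4050, highest other 3). For genes changed at least 2-fold it was also 1 (555, highest other 0). A chance division of interchangeable arrays can therefore be excluded for these counts. Chance differences between cultures cannot, because the labels do not say whether the replicates came from separate cultures. For the lists 12 of 100 gave as many (4, highest other 5), so chance cannot be excluded for the number of lists. Some splits with 3 IL3 arrays in each part gave 3 lists with 0 changed genes. The camera p-values at the preset correlation may therefore be too small.

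The fall of the cell cycle genes was weighed against array quality and culture. With the 3'/5' ratios in the fit 39 of 39 fallen members still fell, with a median of -1.13, and with the level of dim signals the median was -1.18, against -1.17 before. These measures differed little between the groups, as given above, and the 39 members were chosen because they fell. A fit with these measures could therefore take little from the fall. The values show only that the fall does not follow them. The lowest IL3 array lay 0.55 above the highest IL3+SCF array in the mean over these genes, which were chosen because they fell. Over all tested genes of the list the lowest IL3 array had 9.76 and the highest IL3+SCF array 9.41. Culture or harvest conditions shared by a whole group cannot be told apart from SCF, because the labels name no batches.

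Cx3cr1, Plac8, Tmem176a, Tmem176b, Gimap3, Trgv4 and Eomes, known from other blood cells, fell with a median of -3.90. Of 8 other monocyte and macrophage markers tested 3 fell (Lyz1 -1.96, Lyz2 -1.59, Fcgr1 -1.32), Cd68 rose by 1.28 and 4 did not pass (median -0.0947), while 10 untested ones were dim on at least 4 of the 6 IL3 arrays. The Lyz1 probe set is of a kind that may share sequence with other transcripts, so the falls of Lyz1 and Lyz2 may not be independent. The only T and NK cell marker tested, Nkg7, dim on 2 IL3 and 4 IL3+SCF arrays, had -1.40 (adjusted p = 0.0412), and 9 of 10 untested ones were dim on all IL3 arrays. Mcpt8, a basophil marker, had -0.59 (adjusted p = 0.307), or -0.19 (adjusted p = 0.587) without IL3 replicate 1, which had its highest IL3 signal (4782) and the lowest of Cx3cr1 (3901) and Gimap3 (3479), while replicate 4 had the reverse (437, 9025 and 7029). Dim or few markers cannot exclude a small share of cells, though the labels give a purity above 99%. Fewer cells of these 3 types therefore cannot be told apart from a change within the mast cells, which was not tested. Fewer neutrophils or their precursors were not weighed in these tests and stay open too. S100a9 had 2776 and 3475 on IL3 replicates 3 and 6, 51.3 to 516 on the other IL3 arrays and at most 51.0 with SCF. Ngp had 378 and 468 on the same arrays and at most 15.4 with SCF, while Elane and Csf3r were dim on all 6 IL3 arrays.

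The rises of Nrp1 and Cntn4 led to the hypothesis that axon guidance and neuronal adhesion genes rise as a class. Set aside were 9 members whose rise had been seen. Among 39 other tested members 7 rose, or 17.9%, against 18.8% of all other genes (one-sided Fisher exact p = 0.618), and 9 fell. With the 9 included it was 16 of 48, or 33.3%. Setting aside genes because they rose lowers the share in the class but not elsewhere, and including them tests the genes that led to the hypothesis, so neither share decides it.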
